A study of Homo sapiens with 6 samples.

How the data were processed

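Poly(A)-enriched RNA was sequenced from 6 libraries of cells labelled HCC1937, 3 controls and 3 treated with 8 nM docetaxel for 24 h, as paired-end reads of 150 bases on a NovaSeq instrument, per the labels. The authors deposited 1 table of raw read counts per gene, with whole-number counts for 78932 Ensembl gene identifiers and a gene length column. Counts were made with featureCounts 2.0.1 and quality reports with MultiQC 1.11 on genome build GRCh38, per the submitters' processing notes. The aligner, the annotation release, the strand setting and the handling of multi-mapping and overlapping reads are not given in the sources used here. Counts of near-identical paralogs, pseudogenes and overlapping or antisense genes are therefore uncertain. CXCL8, CXCL1 and SOX9 had 0 reads in all 6 libraries, and NUSAP1 and MIF 29 and 43 reads in total, so a low count in this table can also come from the counting. These genes were chosen after their values were seen.

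Columns were assigned to samples by the library names in the labels. Totals ranged from 38622062 to 41675186 counts per library, with the groups compared by an exact two-sided permutation test (p = 0.3, n = 3 each). The groups came from the labels. The labels call the replicates biological but do not say whether they came from separate days or cultures, so p-values measure the spread between these libraries. Within groups, pairs of libraries differed by more than sampling noise, with a Poisson dispersion index between 4.90 and 12.7 over genes with at least 50 summed counts, so no library appeared to be a duplicate of another. The labels do not say that a replicate number marks a shared culture or day, so the comparison carries no block.

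Gene symbols came from a table of Ensembl identifiers and matched 42179 of the 78932 rows and 14951 of the 18040 tested genes. Coordinates and strand came from GENCODE release 29 on GRCh38 and were found for 57356 rows. GC content is that of each gene's longest transcript in the same release, with a value for 91.0% of tested genes and for every tested member of the fixed lists.

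Differential expression used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries scaled by TMM, dispersions estimated with estimateDisp, and groups compared by glmQLFit with robust estimation and glmQLFTest, two-sided. Benjamini-Hochberg adjustment was over the 18040 genes kept, and genes were called at an adjusted p under 0.05. The common biological coefficient of variation was 0.0759. Standard errors are those that give the test's own p, and 95% confidence intervals use the test's degrees of freedom. CPM are TMM-scaled, except the means of EPCAM, CDH1 and the other line markers over all 6 libraries, those of genes too few in reads to test and those in the permutation tests of receptor genes, which use total counts. A further test of the cell line label and 1 single-gene result are not reported here. Receptor genes and library measures were also compared by exact two-sided permutation tests, for which 3 against 3 allows no p below 0.1. There was 1 comparison.

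The 26 gene lists, with 513 members that all matched a gene identifier, were fixed before the data were examined, as were the tests, the rule for naming genes and every alternative except those said to be added. Lists were tested with camera in limma 3.58.1 on voom values with an inter-gene correlation of 0.01, two-sided and adjusted over the 26 lists, each with at least 3 kept genes. Beside it stand camera with an estimated correlation, fry, and counts of called members over all genes and adjusted over the list alone. With an estimated correlation camera called 0 lists, and 1, the immediate early list, had an unadjusted p under 0.05. The estimate was 0.0025 for the immediate early list, 0.229 for the tubulin list and 0.431 for the ribosomal list. In this form camera also takes its degrees of freedom from the libraries and not from the genes. A call can therefore be lost where the genes of a list are not correlated.

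Genes were named by a rule with 3 parts. ESR1, ESR2, GPER1 and PGR were named whatever their result. Named next were the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes that had a symbol other than a clone name, at least 5 CPM on average, and docetaxel values all above or all below the control values. From each list up to 4 members with the smallest p were named. Other genes are said to have been chosen after their values were seen, and some genes the rule names were left out for brevity.

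The alternatives were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, edgeR's glmTreat against a fold of 1.5, and leaving out each library in turn. Added after the data were seen were offsets from a loess fit, with a span of 0.5, of each library's deviation in log2 CPM on GC content and log2 gene length over genes of at least 4 CPM, and offsets on GC content or length alone, and an estimated correlation for the lists in the fits with offsets, without a filter, with library-size scaling or without 1 library. A further 3 gene lists were also chosen after the data were seen and are described under the other observations.

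The code was tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed in the docetaxel group. Of 17593 simulated genes tested, edgeR recovered 53.7% of genes changed 1.25-fold, 79.1% of those changed 1.5-fold and 93.9% of those changed 2-fold, and 3 of its 162 calls were false. With the GC and length trend of the real libraries added to otherwise the same simulation, edgeR without offsets made 1965 calls, of which 1801 were false. With offsets refitted to the simulated counts it made 168 calls, of which 11 were false. The added trend was the loess fit that the offsets themselves use. Its removal was thus built in and does not test the offsets on the real data. Calls that followed the added trend were counted as false by construction, so these counts do not say how many calls in the real data are false. A list changed 1.25-fold in the simulation was called by camera in each version, with 0 other lists called. Simulated genes were drawn independently of each other, so this cannot show how camera behaves where the genes of a list are correlated.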

Results

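Poly(A) RNA was sequenced from 6 libraries labelled HCC1937, a breast cancer cell line that carries a BRCA1 mutation and lacks estrogen receptor, progesterone receptor and HER2 amplification. In 3 libraries the cells had received 8 nM docetaxel for 24 h, and 3 libraries were controls. Docetaxel is a taxane that binds β-tubulin and stabilises microtubules. The labels call the 3 libraries of each group biological replicates. Gene counts totalled 39033097, 41675186 and 41034469 in control replicates 1 to 3, and 38622062, 39069030 and 39181848 in docetaxel replicates 1 to 3. At that depth the upper limit that a count of 0 allows is 3 counts, between 0.0720 and 0.0777 CPM (counts scaled to 1e6 per library), and such limits cover counting error only. A total of 18040 genes had enough counts to be tested, and these held 99.9% of all counts. EPCAM and CDH1, epithelial adhesion genes, averaged 0.0666 and 0.689 CPM over the 6 libraries, although HCC1937 is described as an epithelial line. KRT8 and KRT18, simple epithelial keratins, averaged 1965 and 666 CPM. EPCAM and CDH1 were chosen after their values were seen.

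The comparison of docetaxel with control asked whether the drug raised estrogen receptor expression and the arachidonic acid pathway, which the series title links to it. ESR1, which encodes estrogen receptor α (ENSG00000091831, GRCh38 chromosome 6, 151656691 to 152129619, plus strand), was low in both groups and did not differ between them. It had 65, 52 and 57 reads in the control libraries and 46, 59 and 37 in the docetaxel libraries. These were 1.42 ± 0.22 CPM in control and 1.23 ± 0.30 CPM with docetaxel (SD, n = 3 each). The log2 fold change was -0.20 with a standard error of 0.31, and the 95% confidence interval ran from -0.82 to 0.43, which is 0.57-fold to 1.34-fold (edgeR quasi-likelihood test, adjusted p = 0.75). An exact two-sided permutation test on the CPM of ESR1, here from total counts, gave p = 0.4, and 3 libraries against 3 cannot give a p below 0.1.

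ESR2, which encodes estrogen receptor β (chromosome 14, 64084232 to 64338112, minus strand), had 62, 43 and 30 reads in control and 45, 35 and 47 with docetaxel. Its log2 fold change was 0.00 ± 0.34 (SE, edgeR adjusted p = 1.00), with a sign that depended on the scaling. GPER1, a membrane-bound estrogen receptor (chromosome 7, 1082208 to 1093815, plus strand), had the most reads of the receptor genes, at 10.9 ± 0.7 CPM in control and 11.9 ± 0.1 CPM with docetaxel (SD, n = 3 each). Its log2 fold change of 0.12 ± 0.11 (SE) missed the threshold (edgeR adjusted p = 0.52), and with the GC and length offsets described below it was -0.04. PGR, the progesterone receptor gene and a classical estrogen receptor target (chromosome 11, 101029624 to 101130524, minus strand), had 0 reads in every control library and 3, 0 and 0 reads in the docetaxel libraries, too few to test. As a list, 0 of the 3 estrogen receptor genes passed edgeR's test, 0 passed at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 (camera adjusted p = 0.945). The list's median log2 fold change was slightly above 0 and its mean was -0.03.

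**Figure D1:**
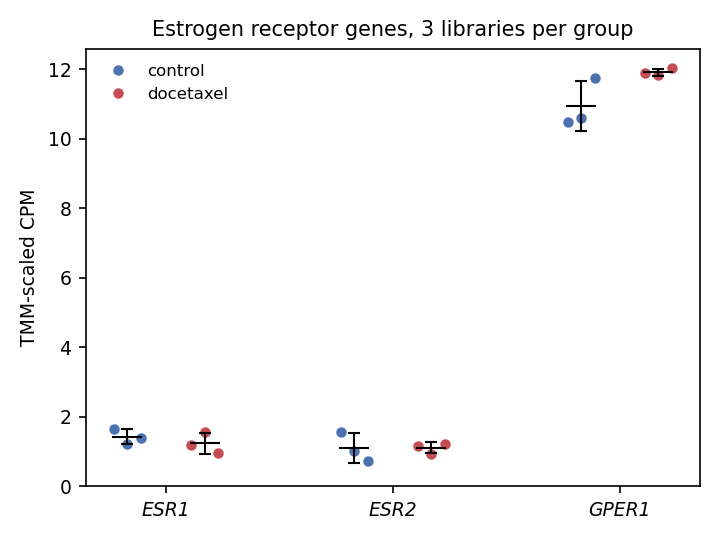
CPM of the 3 estrogen receptor genes in each library (y axis, TMM-scaled CPM), with blue points for control and red points for docetaxel; bars give the mean and SD of 3 libraries. ESR1 lies between 0.96 and 1.65 CPM in all 6 libraries, with the groups overlapping.

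Among called genes with a symbol, at least 5 CPM on average and no overlap between the groups, the 4 that rose most with docetaxel were transcription factors of the immediate early response. EGR1, a zinc finger transcription factor (chromosome 5, 138465490 to 138469315), rose 8.05-fold, from 3.08 ± 1.00 to 24.8 ± 1.3 CPM (SD, n = 3 each). FOS, a subunit of the AP-1 dimer (chromosome 14, 75278774 to 75282230), rose 4.17-fold, from 16.7 ± 0.3 to 69.5 ± 2.5 CPM, and its relative FOSB rose 3.99-fold. JUN, which pairs with FOS proteins in AP-1, rose 2.85-fold and its relative JUNB 1.67-fold. Their edgeR adjusted p values ran from 8.44e-22 for FOS to 1.49e-08 for FOSB. GDF15, a secreted stress cytokine, rose 1.84-fold and CCN2, a matricellular growth factor, 1.66-fold. PDE2A, a cyclic nucleotide phosphodiesterase, rose 1.59-fold, CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 1.57-fold, and NOXA1, an activator of NADPH oxidase, rose 1.53-fold.

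Among called genes held to the same limits, the largest fall was in CA9, a carbonic anhydrase known as a hypoxia-inducible gene (chromosome 9, 35673856 to 35681159). It went from 6.99 ± 0.29 to 3.07 ± 0.34 CPM (SD, n = 3 each), a log2 fold change of -1.19 ± 0.16 (SE, edgeR adjusted p = 6.76e-06). PM20D2, a peptidase, followed at a log2 fold change of -0.91, and IFT80, a component of intraflagellar transport, at -0.79. VGLL3, a cofactor of TEAD transcription factors, was at -0.72 and SECISBP2L, a paralog of a selenocysteine insertion factor, at -0.71. FBXO30, a ubiquitin ligase component, was at -0.70, with MANEA, a Golgi endomannosidase, and EEA1, an early endosome tether, both at -0.69. FAM135A was at -0.68, and SASS6, which builds the centriole cartwheel, at -0.67. In each of these genes the 3 docetaxel libraries all lay on the same side of the 3 control libraries, as the naming rule required. All of them passed the test, which the rule also required. With GC and length offsets NOXA1, FBXO30 and MANEA no longer passed (edgeR adjusted p of 0.17, 0.055 and 0.13).

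**Figure D2:**
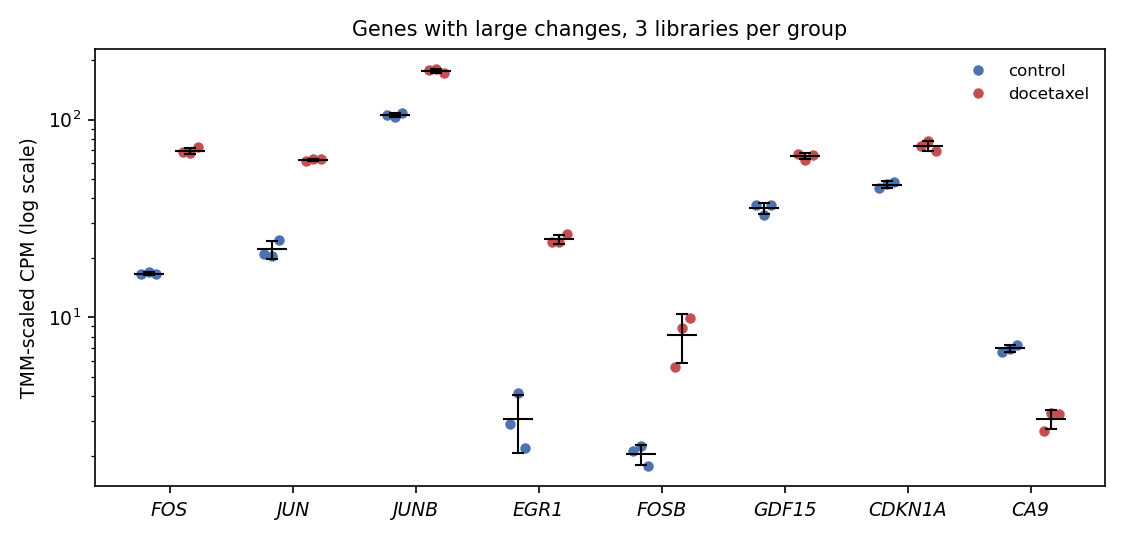
CPM of 8 genes in each library (y axis, TMM-scaled CPM on a log scale), with blue points for control and red points for docetaxel; bars give the mean and SD of 3 libraries. For FOS the control libraries average 16.7 CPM and the docetaxel libraries 69.5 CPM, and for CA9 the averages are 6.99 and 3.07 CPM.

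In total, 1649 genes were higher and 1410 lower with docetaxel at an adjusted p under 0.05 by edgeR, of the 18040 tested. Most changes were small. The median called gene differed by 1.19-fold, while 68 genes rose and 76 fell by 1.5-fold or more, and 35 rose and 23 fell by 2-fold or more. Tested against a fold of 1.5 with edgeR's glmTreat, 6 genes were higher, among them EGR1, FOS, FOSB, JUN and GDF15. In that test 0 genes were lower, with 60 lower at an unadjusted p under 0.05. The docetaxel and control libraries did not overlap in 32.0% of tested genes, where chance gives 10% on average. Genes that share a trend between libraries, such as that with GC content below, separate together. The share by chance can thus lie far from 10%, and the excess is not a test of a drug effect. Scaling by library size alone gave 1096 genes higher and 1866 lower. Without control replicate 2 the counts were 990 higher and 740 lower, without docetaxel replicate 2 they were 1089 and 968, and without docetaxel replicate 3 they were 1056 and 768.

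The direction of change followed the GC content of the transcript. Genes called higher had a median GC content of 60.2%, genes called lower 39.5%, and the other tested genes 48.7%. Over 10776 genes the log2 fold change correlated with GC content (Spearman's rho = 0.74, Pearson's r = 0.69), a relation across genes, which are not independent replicates. In the fifth of genes with the lowest GC content the median log2 fold change was -0.20, with 6 genes called higher and 863 lower, and in the fifth with the highest it was 0.18, with 1018 higher and 4 lower. Each library's log2 CPM was also taken as a deviation from the gene's mean over all 6 libraries. Its slope on GC content was negative in the 3 control libraries and positive in the 3 docetaxel libraries. The slopes of the groups did not overlap (exact two-sided permutation p = 0.1, the smallest possible). They are relative to the average of the 6 libraries, so their signs do not give each library's own GC bias. When a smooth trend on GC content and gene length was fitted in each library and entered as offsets, an alternative chosen after the data were seen, edgeR called 468 genes higher and 310 lower. Of the 3059 genes called without offsets, 448 were also called with them. The counts with these offsets are given beside each gene list below.

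**Figure D3:**
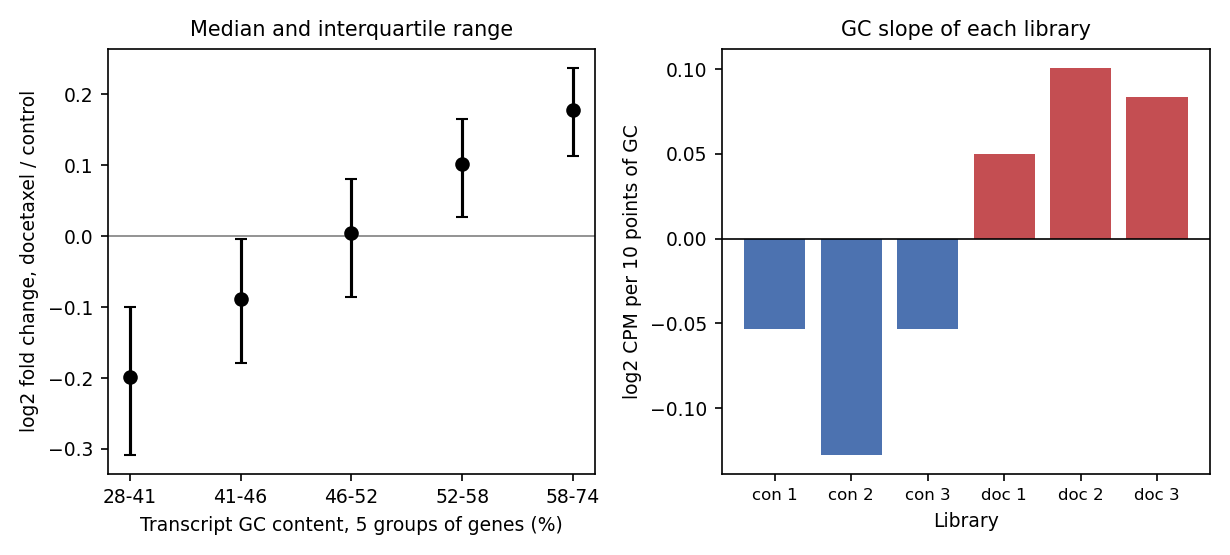
Left, median log2 fold change of docetaxel over control (y axis) in 5 equal groups of genes by transcript GC content (x axis, %), with bars for the interquartile range; it runs from -0.20 to 0.18. Right, the GC slope of each library (y axis, log2 CPM per 10 points of GC), in blue for the 3 control libraries, all below 0, and in red for the 3 docetaxel libraries, all above 0. Slopes are of log2 CPM as a deviation from each gene's mean over the 6 libraries, so 0 stands for their average.

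Of 26 gene lists fixed before the data were examined, camera called 3, all toward higher expression. Where a count "adjusted over the list alone" is not given below, it was equal to the count over all genes tested. The list with the smallest p was that of immediate early and AP-1 genes, of which 9 of 23 tested members rose and 2 fell (camera adjusted p = 1.51e-07). With an estimated correlation between genes the call was lost (adjusted p = 0.0861). Adjusted over the list alone, 11 rose and 2 fell. FOS, EGR1, JUN and JUNB had the smallest p values. The median log2 fold change of the 23 was 0.12, and 0.10 with GC and length offsets, and the mean was 0.49. Without 1 library the median was 0.13 to 0.18, and over 14 alternative fits 0 to 2 members were lower. With GC and length offsets 7 members were higher and 1 lower, and the log2 fold changes of EGR1 and FOS were 2.90 and 1.99.

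Tubulin genes, whose products form the microtubules that docetaxel binds, were the list with the largest share of members called. Of 16 tested members 9 rose and 0 fell (camera adjusted p = 2.76e-05, adjusted p = 0.416 with an estimated correlation). TUBA1A rose 1.32-fold, from 20.9 ± 0.6 to 27.6 ± 0.7 CPM (SD, n = 3 each), and TUBB4B, TUBA1C and TUBA1B rose 1.18-fold, 1.15-fold and 1.15-fold. With GC and length offsets 4 members were higher and 0 lower, and TUBB4B and TUBA1B no longer passed. Tubulin genes are near-identical in sequence, so reads could be split or dropped among them. Ribosomal protein genes were the remaining called list, with 10 of 26 members higher and 0 lower (camera adjusted p = 3.50e-05, adjusted p = 0.484 with an estimated correlation). Adjusted over the list alone, 11 were higher. RPS9, RPS2, RPLP1 and RPLP0 rose by 0.19, 0.16, 0.16 and 0.16 on the log2 scale, and with offsets 2 members were higher and 1 lower. Without docetaxel replicate 2 camera called 2 lists and the ribosomal list was not among them, and without control replicate 2 it called 5. With GC and length offsets it called 8: these 3 (adjusted p of 1.75e-06 for immediate early, 0.0014 for tubulin and 0.017 for ribosomal protein genes) and the mitotic, interferon, NRF2, p53 target and cytochrome P450 lists, whose values follow. With offsets and an estimated correlation it called 0, with 4 at an unadjusted p under 0.05, and those 3 had an adjusted p = 0.137, 0.476 and 0.540.

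Among 19 tested estrogen receptor target genes, 3 rose and 3 fell (camera adjusted p = 0.945). CTSD, the lysosomal protease cathepsin D, rose 1.16-fold and NHERF1, a scaffold protein, rose 1.12-fold, while SLC7A2, a cationic amino acid transporter, fell by 0.48 and CCND1, which encodes cyclin D1, fell by 0.18 on the log2 scale. With GC and length offsets 0 were higher and 1, CCND1, was lower. The CCND1 call was lost without control replicate 2 or 3 (edgeR adjusted p of 0.22 and 0.053) or docetaxel replicate 2 or 3 (0.15 and 0.12). The list's median log2 fold change was 0.01 and its mean was -0.04. SLC7A2 was no longer called without control replicate 1 (0.057), and NHERF1 was not called without control replicate 1 or docetaxel replicate 3 (0.053 and 0.083).

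Of 11 luminal epithelial markers 3 rose and 0 fell (camera adjusted p = 0.227), and 1 was higher with offsets. Without control replicate 1 or docetaxel replicate 3 only 1 was called, and ELF3, an epithelial transcription factor, lost its call in 6 of 14 alternative fits. KRT8, an abundant simple epithelial keratin, went from 1812 ± 61 to 2127 ± 34 CPM (SD, n = 3 each), and its partner KRT18 rose by 0.15 on the log2 scale. Of 10 basal epithelial markers 4 rose and 0 fell (camera adjusted p = 0.192), and 1 was higher with offsets. LAMB3, a laminin-332 chain, rose 1.42-fold, SFN, the 14-3-3σ protein, 1.21-fold, and COL17A1, a hemidesmosome collagen, 1.47-fold. The basal list had a median log2 fold change of -0.03 and a mean of 0.14. KRT19, KRT5, KRT14, CLDN3, ESRP1 and TP63, which belong to these lists and mark epithelial cells, had too few reads to test, with means between 0.0172 and 0.127 CPM over the 6 libraries. These 6 were chosen after their values were seen. Of 15 mesenchymal transition genes 3 rose and 1 fell (camera adjusted p = 0.884), with COL5A1, a fibrillar collagen, 1.16-fold higher and LOX, which crosslinks collagen, lower by 0.47 on the log2 scale. Over the 14 fits 1 to 3 were higher and 1 to 3 lower. With offsets 0 of these 15 were called, and 4 had an unadjusted p under 0.05. KRT18 was not called without control replicate 1 or docetaxel replicate 3 (edgeR adjusted p of 0.067 and 0.079), and COL17A1 was not called without docetaxel replicate 3 (0.087).

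Of 39 tested genes in the 5 lists of arachidonic acid release, conversion and eicosanoid receptors 5 were called, against 3059 of all 18040 tested genes. Phospholipase A2 enzymes free arachidonic acid from membrane lipids, and 2 of 11 tested members rose while 0 fell (camera adjusted p = 0.869). PLAAT3, a phospholipase A and acyltransferase, rose 1.14-fold, from 96.8 ± 2.2 to 110.5 ± 6.3 CPM (SD, n = 3 each, edgeR adjusted p = 0.0064). PLA2G15, the lysosomal phospholipase A2, rose 1.18-fold at an adjusted p of 0.042 and was not called in 10 of 14 alternative fits, among them DESeq2 (0.064), or with offsets (0.62). With offsets 1 member, PLAAT3, was higher, and PLAAT3 was not called without docetaxel replicate 2 or 3 (0.067 and 0.055).

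Of 10 cyclooxygenase and prostaglandin synthesis genes, 1 rose and 0 fell (camera adjusted p = 0.521). It was PTGES2, a prostaglandin E synthase, at 1.18-fold, and with offsets 0 members were called by edgeR, with 1 at an unadjusted p under 0.05. Fry, which tests a list against no change and not against other genes, called the cyclooxygenase list toward higher expression (adjusted p = 0.011). It was run without offsets only. Of 10 lipoxygenase and leukotriene synthesis genes 0 were called by edgeR, 0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom (camera adjusted p = 0.734). The smallest p among them was that of GGT5, a γ-glutamyl enzyme that acts on leukotriene C4, with a log2 fold change of 0.54 ± 0.32 (SE, edgeR adjusted p = 0.28). Only 3 members of the cytochrome P450 arachidonate list had enough reads to test. They were CYP1B1, CYP1A1 and EPHX1, an epoxide hydrolase and not a P450. Of these only CYP1B1 was called. It fell by 0.40 on the log2 scale, from 67.8 ± 2.7 to 51.5 ± 4.3 CPM (SD, n = 3 each, list camera adjusted p = 0.334). No other P450 of the list was tested, so calls of the list do not speak for that branch as a whole. CYP1B1 was also lower with offsets, and with them camera called the list toward lower expression (adjusted p = 0.024, adjusted p = 0.270 with an estimated correlation). Fry called the cytochrome P450 list toward lower expression without offsets (adjusted p = 0.030). The phospholipase A2, lipoxygenase and eicosanoid receptor lists were not called by fry (adjusted p of 0.46, 0.19 and 0.24). Of 5 eicosanoid receptors 1, the leukotriene B4 receptor LTB4R, rose 1.20-fold and 0 fell (camera adjusted p = 0.560). Adjusted over the list alone, 2 rose, and with offsets 0 were called, with 1 at an unadjusted p under 0.05. LTB4R was not called without control replicate 1 or 2 or docetaxel replicate 2 or 3 (edgeR adjusted p of 0.11, 0.094, 0.091 and 0.070).

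Lipid synthesis genes moved in both directions. Of 18 genes of polyunsaturated fatty acid synthesis and acylation, 2 rose and 4 fell (camera adjusted p = 0.917), or 4 and 4 adjusted over the list alone. FADS3, a member of the fatty acid desaturase family, rose 1.20-fold, while ELOVL5, an elongase of polyunsaturated fatty acids, ACSL4, an acyl-CoA synthetase that prefers arachidonic acid, and SCD, the stearoyl-CoA desaturase, fell by 0.22, 0.24 and 0.14 on the log2 scale. With offsets FADS3 was higher and SCD lower. Of 24 cholesterol synthesis genes 8 rose and 4 fell (camera adjusted p = 0.227), or 9 and 4 adjusted over the list alone. MVD, FDPS and LSS, enzymes of the mevalonate and sterol steps, rose 1.22-fold, 1.19-fold and 1.18-fold, and MSMO1, a sterol methyl oxidase, fell by 0.32 on the log2 scale. With offsets 3 cholesterol genes were higher and 1 lower, and of those named here only FDPS was among them.

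**Figure D4:**
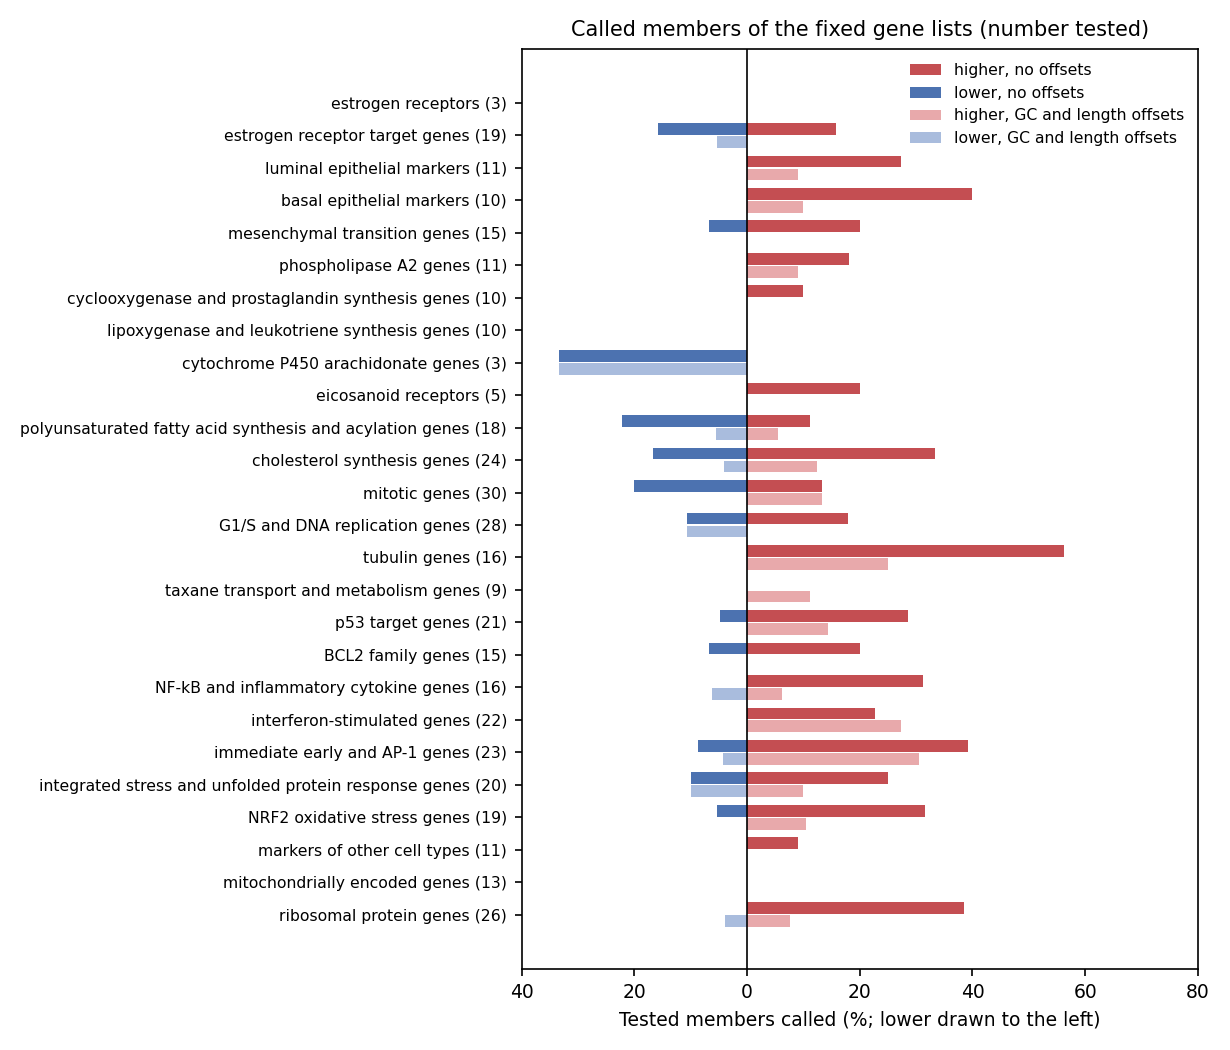
Share of tested members called higher (red, right of 0) and lower (blue, left of 0) in each fixed list (x axis, %; y axis, list and number tested), in dark colours without and in light colours with GC and length offsets. Without offsets tubulin genes have the largest share higher, 9 of 16. With offsets they have 4 of 16, a smaller share than immediate early genes (7 of 23) and interferon genes (6 of 22).

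Cell cycle genes also split. Of 30 mitotic genes 4 rose and 6 fell (camera adjusted p = 0.850), or 6 and 9 adjusted over the list alone. Over the 14 fits 2 to 4 were higher and 1 to 10 lower. CDC20, the activator of the anaphase-promoting complex, and AURKB, a mitotic kinase, rose 1.17-fold and 1.13-fold, and CDK1 and TOP2A, the mitotic kinase and a DNA topoisomerase, fell by 0.22 and 0.16 on the log2 scale. With offsets 4 mitotic genes were higher and 0 lower, with none of those named here called and CDK1 and TOP2A at 0.00 and 0.02, and camera called the mitotic list toward higher expression (adjusted p = 0.0047, adjusted p = 0.178 with an estimated correlation). The CDK1 call was also lost without control replicate 2 (edgeR adjusted p = 0.057). The list's median log2 fold change was 0.02 and its mean was -0.05. Of 28 genes of G1/S and DNA replication 5 rose and 3 fell (camera adjusted p = 0.948), and 0 and 3 with offsets. MCM10, a replication initiation factor, fell by 0.43 and UHRF1, a regulator of DNA methylation, by 0.22 on the log2 scale, while MCM7, a helicase subunit, and CDT1, a licensing factor, each rose 1.13-fold. With offsets CDT1 was at -0.03.

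Of 21 tested p53 target genes 6 rose and 1 fell (camera adjusted p = 0.192), or 6 and 3 adjusted over the list alone. CDKN1A went from 47.0 ± 1.8 to 73.6 ± 4.2 CPM (SD, n = 3 each), FDXR, a mitochondrial ferredoxin reductase, rose 1.34-fold, BAX, which permeabilises mitochondria, rose 1.22-fold, and RRM2B, a ribonucleotide reductase subunit, fell by 0.39 on the log2 scale. With offsets 3 members were higher, among them CDKN1A and FDXR, and camera called the list toward higher expression (adjusted p = 0.024, adjusted p = 0.270 with an estimated correlation). Of 15 BCL2 family genes 3 rose and 1 fell (camera adjusted p = 0.227), or 4 and 1 adjusted over the list alone. BAX and BOK, pore-forming members, and BBC3, the BH3-only protein PUMA, rose 1.22-fold, 1.24-fold and 1.28-fold, and PMAIP1, the BH3-only protein NOXA, fell by 0.28 on the log2 scale. With offsets 0 of the 15 were called, with 1 at an unadjusted p under 0.05. PMAIP1 was not called without control replicate 2 or 3 or docetaxel replicate 2 or 3 (edgeR adjusted p of 0.27, 0.076, 0.14 and 0.15), nor BBC3 without docetaxel replicate 2 (0.060). Of 9 genes of taxane transport and metabolism 0 were called by edgeR, 0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom (camera adjusted p = 0.850). With offsets the efflux pump gene ABCG2 was called, at a log2 fold change of 0.23.

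Interferon-stimulated genes had 5 of 22 tested members higher and 0 lower (camera adjusted p = 0.122), and 6 higher with offsets, where camera called the list toward higher expression (adjusted p = 0.0047, adjusted p = 0.178 with an estimated correlation). ISG15, a ubiquitin-like modifier, went from 33.1 ± 1.3 to 48.7 ± 3.3 CPM (SD, n = 3 each), and OASL, IFIT3 and IFIT2, antiviral effectors, rose 1.30-fold, 1.39-fold and 1.36-fold. IFIT2 was not called without docetaxel replicate 2 (edgeR adjusted p = 0.058). Of 16 NF-κB and inflammatory cytokine genes 5 rose and 0 fell (camera adjusted p = 0.129), or 1 and 1 with offsets. DESeq2 and limma-voom each called 3 of them, and of the called members RELB and IL11 lost their call in 3 and 8 of 14 alternative fits. NFKB2, an NF-κB subunit, rose 1.20-fold, and the cytokine IL32 rose 2.45-fold at a low level, from 0.98 ± 0.54 to 2.43 ± 0.32 CPM (SD, n = 3 each). Of 19 NRF2 oxidative stress genes 6 rose and 1 fell (camera adjusted p = 0.122), or 7 and 1 adjusted over the list alone. TKT, transketolase, rose 1.15-fold and HMOX1, heme oxygenase 1, rose 1.28-fold. With offsets 2 members were higher and camera called the list toward higher expression (adjusted p = 0.011, adjusted p = 0.476 with an estimated correlation). Of 20 genes of the integrated stress and unfolded protein response 5 rose and 2 fell (camera adjusted p = 0.690), or 5 and 3 adjusted over the list alone and 2 and 2 with offsets. PHGDH and PSAT1, consecutive enzymes of serine synthesis, went in opposite directions, at log2 fold changes of 0.23 and -0.23, and PPP1R15A, a phosphatase subunit that reverses the stress response, rose 1.34-fold.

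Of 11 tested markers of other cell types 1 rose and 0 fell (camera adjusted p = 0.695). It was CD14, a monocyte marker, at 1.48 ± 0.17 CPM in control and 2.52 ± 0.64 CPM with docetaxel (SD, n = 3 each, edgeR adjusted p = 0.038). Adjusted over the list alone 0 were called, DESeq2 and limma-voom called 0, the CD14 call was lost in 10 of 14 alternative fits, and with offsets 0 were called, with 3 at an unadjusted p under 0.05. COL1A1, a fibroblast collagen, was at 137 ± 2 CPM in control and 143 ± 3 CPM with docetaxel (edgeR adjusted p = 0.38). Of 13 mitochondrially encoded genes 0 were called by edgeR, 0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom (camera adjusted p = 0.734), and 2 were lower with library-size scaling or without docetaxel replicate 1, and 1 without docetaxel replicate 2. The median of that list was 0.01 and its mean -0.02. Mitochondrial messenger RNA made up 10.7 ± 0.3% of counts in control and 10.4 ± 0.2% with docetaxel (SD, n = 3 each, exact two-sided permutation p = 0.3).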

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

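The tests with GC or length offsets, and those with an estimated correlation in any fit but the main one, were chosen after the results were seen, and the others before. ESR1 missed the threshold in every fit, with log2 fold changes from -0.24 with library-size scaling to -0.13 with GC and length offsets, and from -0.40 to -0.046 when 1 library was left out. The 1649 higher and 1410 lower genes became 1096 higher with library-size scaling (1866 lower), 468 and 310 with GC and length offsets, 448 and 318 with GC offsets alone, and 6 and 0 with edgeR's glmTreat against a fold of 1.5, where 60 were lower at an unadjusted p under 0.05. Leaving out 1 library in turn gave 990 to 1397 higher and 740 to 1841 lower. The low values came without control replicate 2 (990 and 740) and without docetaxel replicate 2 (1089 and 968) or 3 (1056 and 768). These libraries had the GC slopes farthest from the average of the 6 libraries, at -0.127, 0.101 and 0.084 log2 CPM per 10 points of GC. The cause was not tested. Other scalings, filters and tools, and length offsets alone, gave counts within 1.5 times of 1649 and 1410. Camera called 3 lists, against 7 with no filter on low counts, 8 with GC and length offsets, 0 with an estimated correlation, where 1 had an unadjusted p under 0.05, and 2 to 5 with 1 library left out (5 without control replicate 2). Lists gained were luminal, cholesterol, NF-κB and NRF2 with no filter, mitotic, p53 target, interferon, NRF2 and cytochrome P450 with the offsets, basal and NRF2 without control replicate 2, interferon without docetaxel replicate 3, and mitochondrially encoded genes with library-size scaling. With an estimated correlation 0 were called in each of these fits, with 1 to 4 at an unadjusted p under 0.05. Fry, which tests each list against no change and not against other genes, called 12 and did not call the ribosomal list (adjusted p = 0.187). Those toward higher expression were the immediate early, tubulin, interferon, luminal, basal, p53 target, cyclooxygenase, cholesterol, NF-κB, NRF2 and BCL2 lists. The cytochrome P450 list was called toward lower expression. Over the 14 alternative fits, members called higher ran from 1 to 3 of estrogen target and fatty acid genes, 0 to 2 of phospholipase A2 and eicosanoid receptor genes, 2 to 5 of G1/S and NF-κB genes and 6 to 11 of ribosomal genes, and members called lower from 1 to 3 of estrogen target, p53 target and integrated stress genes, 2 to 5 of cholesterol genes, 0 to 2 of NRF2 and ribosomal genes and 0 to 1 of phospholipase A2, cyclooxygenase and BCL2 genes. Why these list counts differed was not tested. limma-voom was not run as a separate alternative for the lists, since camera already used voom values. With the replicate block the counts were 1283 higher, 1106 lower and 3 lists, and CCND1 and PMAIP1 had an adjusted p of 0.074. The labels do not say whether the numbers pair the libraries. The deviations of same-numbered libraries correlated at -0.11, -0.13 and 0.07, which gave no sign of pairing. Among named genes, none called without offsets changed sign under any alternative fixed before the data were examined. ESR2 was at -0.0082 with RLE scaling, -0.037 with library-size scaling, -0.011 with DESeq2 and between -0.22 and 0.34 with 1 library left out, EPHX1 at -0.0011 with library-size scaling and between -0.0014 and 0.054, CYP1A1 between -0.62 and 0.046 and ALOXE3 between -0.065 and 0.49 with 1 library left out. With GC and length offsets GPER1 was at -0.045, NHERF1 at -0.012, EPHX1 at -0.082, CDK1 at 0.0042, TOP2A at 0.024, CDT1 at -0.028 and COL1A1 at -0.088. With those offsets 45 of 87 called named genes lost their call, 4 of them with a change of sign, 1 gained a call and 3 that were called in neither fit changed sign, and the cause was not tested apart from the offsets' own construction. Depth limits genes near 1 CPM, such as ESR1 with 37 to 65 reads per library.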

Other observations

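The 3 gene lists in the next 2 paragraphs, and the tests of GC content and single libraries further on, were chosen after the results were seen; only the other splits of the libraries were planned before. Proteasome subunit genes, which encode the protease that degrades ubiquitinated proteins, were added to the lists and 9 of 31 tested members rose while 1, PSMA1, fell (camera adjusted p = 0.00786 over 29 lists, adjusted p = 0.432 with an estimated correlation). PSMD4, a ubiquitin receptor, rose by 0.23 ± 0.04 and PSMA5, a core subunit, by 0.17 ± 0.04 on the log2 scale (SE). With GC and length offsets 9 were higher and 1 lower, of which 3 and 1 were those called without them, with a camera adjusted p of 7.47e-09 (adjusted p = 0.334 with an estimated correlation), and the log2 fold changes of PSMA5, PSMD14 and PSMC2 were 0.40, 0.38 and 0.28.

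Hypoxia-inducible genes were added because CA9 had fallen most among the named genes. Of 20 tested members 5 fell and 1, EGLN1, rose (camera adjusted p = 0.0971, adjusted p = 0.416 with an estimated correlation). Besides CA9, at a log2 fold change of -1.19, the members that fell were INSIG2, PFKFB4, MXI1 and BNIP3, at -0.47, -0.34, -0.26 and -0.26. With offsets 3 were lower and 2, EGLN1 and PGK1, were higher (camera adjusted p = 0.0229, toward lower, adjusted p = 0.251 with an estimated correlation). Of 19 tested YAP and TEAD target genes 3 rose and 1 fell (camera adjusted p = 0.262). With offsets the same 3 were higher, while PTPN14 lost its call as lower (edgeR adjusted p = 0.14) and FJX1 gained one (0.044). ANKRD1, a muscle ankyrin repeat protein also known as a YAP target, was near the floor, with 0, 1 and 3 reads in the control libraries and 21, 21 and 16 with docetaxel (edgeR adjusted p = 0.0013). CCN2 and CCN1, matricellular proteins, had log2 fold changes of 0.73 ± 0.16 and 0.41 ± 0.05 (SE, edgeR adjusted p of 0.0012 and 2.58e-07). These lists were picked because some of their members had moved, so their tests are not independent evidence.

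The count of called genes was 3059 for docetaxel against control, and the highest count for another split of the 6 libraries into 3 and 3 was 1. The real split was the only 1 of 10 to reach its count. Other splits put libraries of both groups on each side, so any difference between the groups adds to the spread within a side. The contrast therefore does not tell a drug effect from another difference between the groups. For the fixed lists the real split called 3, the highest other called 3, and 2 of the 10 splits gave as many. With 10 splits no share under 0.05 can be reached.

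The change with docetaxel followed GC content across genes. Library totals were too close for thinning to test a difference in library size. Gene length bias did not account for the trend, since Spearman's rho with GC content was 0.692 with length offsets alone, against 0.744. Variation between libraries in the recovery of GC-rich fragments is a candidate explanation. Control replicate 2 differed from the other control libraries with a rho of -0.495 with GC content, a size of 0.495 between libraries of the same treatment. This was the largest, and the remaining libraries had a rho between -0.261 and 0.295 against their own group. A response of GC-rich transcripts to docetaxel cannot be told apart from it: the GC slopes of the 3 control and 3 docetaxel libraries did not overlap, but the exact permutation p is 0.1, the smallest that 6 libraries allow.

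Of the 23 tested members of the fixed immediate early and AP-1 list 9 rose and 2 fell, with a median log2 fold change of 0.122, 0.131 to 0.184 with 1 library left out, and 0.101 with GC and length offsets. Camera still called the list with those offsets (adjusted p = 1.75e-06, adjusted p = 0.137 with an estimated correlation), with 7 members higher by edgeR. In these members the fitted trend thus did not take up the whole rise. Camera called it in each of the 6 fits that left out 1 library, at an adjusted p of 6.06e-07 or less. The largest adjusted p with an estimated correlation was 0.366. The median stayed above 0 in each of these fits, so its rise did not rest on a single library. At its preset correlation camera also called up to 3 lists in other splits of the libraries, so its calls alone do not decide on either cause. Immediate early genes also respond to handling, serum and medium change, and how the cultures were handled before lysis was not analysed here. That explanation stays open, as does a response to docetaxel.

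EPCAM averaged 0.0666 CPM and CDH1 0.689 CPM over the 6 libraries labelled HCC1937, a line described as epithelial, while VIM averaged 362 CPM and CDKN2A 436 CPM. KRT19, KRT5 and KRT14 averaged 0.105, 0.0386 and 0.127 CPM, and KRT8 and KRT18 averaged 1965 and 666 CPM. These genes were chosen after their values were seen. CXCL8 and SOX9 had 0 counts, and the handling of shared reads is not given in the sources used here. Whether the libraries match the labelled line is left open.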
